A study of Mus musculus with 10 samples.

How the data were processed

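H3K27ac ChIP libraries of LSK cells from 4 Fli-1 knockout and 4 wild-type samples each had a MACS2 narrowPeak list. The 2 input samples were not analysed here. Per the labels' protocols, sorted nuclei were digested with MNase and libraries made with a KAPA kit. Per the submitters' processing notes, the tools were FastQC 0.11.8, Trim Galore 0.6.4, Bowtie2 2.3.5, Picard 2.21.1, SAMtools 1.9 and MACS2, with the genome build mm10. The MACS2 version, its settings and the control used for each call are not given in the sources used here. Each of the 8 samples has its own deposited list.

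The lists give, as the authors deposited them, a fold over background (a ratio), a −log10 p and a −log10 q, and a score that MACS2 derives for display, with a summit offset. These are each peak's own values within its library, and were used only to rank, filter or describe peaks of that list. The lowest −log10 q of the lists corresponds to a q of 0.05. Positions were converted to 1-based coordinates.

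Read totals are not in the lists. Relative depth was recovered from the authors' fold and −log10 p values by inverting the Poisson formula of MACS2 with its pseudocount of 1. The background rate shared by most peaks and the step between pileup values gave the density at which peaks were called and the ChIP fragment density, taking the shortest peak as the fragment length. Of the pileup values at the background rate, at least 99.7% in every library lay within 0.02 of a whole step. Calling density was 2.92 per kb in KO library 1, 5.25 in the other KO libraries, 2.43 in WT library 1 and 4.62 in the other WT libraries. On simulated peaks the recovery returned the true rate and step. Replicates numbered 1 had the lowest depth and the shortest fragments, 168 and 151 bp.

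The comparisons used the 4233 strongest peaks per library by −log10 q, ties by fold and then position, because the shortest list held 4233. The lists as deposited were analysed beside them. Gene positions came from an annotation table of the same assembly (GRCm38.p6), with 49943 placed genes, 21887 of them protein-coding. It gives no strand and no exons. The planned promoter window around a transcription start was therefore replaced by 1 kb around either annotated end of the gene, so a gene-end peak can be at the start or the end of transcription, and a start inside the annotated gene is missed, as for Fli1. A peak within the windows of neighbouring genes counts for each. All 845 list memberships, 785 genes in 28 lists, were found by symbol.

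Single values per library were compared by the exact two-sided permutation test of the difference of means over all 70 assignments. Gene lists were compared by the log2 odds ratio of a gene-end peak in members against other genes, with 0.5 added to each cell, and by the share of peaks within 50 kb of members. Genes and regions with a peak in all 4 libraries of one genotype and none of the other were counted, and the count was made for all 35 splits of the libraries. Fisher's exact test, two-sided, was applied per gene and region, with Benjamini-Hochberg adjustment. With 4 against 4 libraries its smallest p is 0.0286, so no single gene can pass adjustment unless a large part of the genes do, and adjusted over the list alone no list had a passing gene. A limma test of rank scores, the log2 of the list length plus 1 over the rank, and 0 for no peak, was added after the data were seen for 5570 genes with a peak in at least 2 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.

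On simulated gene ranks of 7027 genes with 200 changed genes, shifts of 2, 4 and 6 on the log2 rank scale put 113, 197 and 200 of them at 4 against 0 libraries, and limma called 0, 173 and 200 of them in the right direction. With no change 21 genes were at 4 against 0 and limma called 0. The simulated libraries all had the same number of marked genes and the same noise, and the changed genes had middling mean scores. The real libraries differed in these respects, so the simulated counts do not give their error or detection rates.

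Named genes followed a rule fixed before the data were examined. It took Fli1, up to 12 protein-coding genes per direction at 4 against 0 libraries (members of a fixed list first, then by mean rank), up to 4 members per list with the largest difference in libraries, and up to 10 domain genes per direction. Alternatives were the lists as deposited, lists of 2116 peaks, ranking by fold, a −log10 q of at least 5, windows of 2.5 kb, protein-coding genes, autosomes, an overlap of 50% of a peak, each library left out and the replicate number as a block. Whole gene bodies, peak summits, regions covered to at least 50% by a library, limma and omission of both replicates numbered 1 were added after the data were seen. A planned comparison of 16 sequence motifs was not run, because no genome sequence was used here.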

Results

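H3K27ac, the histone mark of active promoters and enhancers, was mapped by ChIP in mouse bone marrow LSK cells. LSK cells (lineage negative, Sca1 and Kit positive) are the fraction that holds haematopoietic stem and progenitor cells. The cells had been co-cultured for 6 days with E4orf1 endothelial cells, a vascular niche line, and compared cells in which 4-OHT had induced deletion of Fli-1, an ETS-family transcription factor, with wild-type (WT) cells. There were 4 knockout (KO) and 4 WT libraries, each with its own peak list. An input library of each genotype was not analysed here. Nothing in the labels says that the libraries of a genotype came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. The question was which promoters and regions carry H3K27ac with and without Fli-1. In all tests of single values the smallest exact permutation p with 4 against 4 libraries was 0.0286.

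The targeted gene was described first. Fli1 (chromosome 9, 32422204 to 32543432, mm10) had peaks inside the annotated gene in all 8 lists as deposited, such as 32539511 to 32541437 in KO library 4 and 32540622 to 32541326 in WT library 4. KO libraries 1 to 4 had 6, 16, 9 and 14 peaks in the gene and 10 kb either side, and WT libraries 1 to 4 had 3, 1, 1 and 1. Among the 4233 strongest peaks of each library, no KO library had a peak there. WT library 1 had 2 peaks there, WT library 2 had 1, and WT libraries 3 and 4 had 0. A histone peak does not read a deleted exon, so these values neither verify nor contradict the genotype labels.

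The KO libraries had more H3K27ac peaks than the WT libraries. KO lists held 14303, 30479, 13225 and 23045 peaks, a mean of 20263 ± 8107 (SD, n = 4). WT lists held 6559, 4233, 6877 and 8147 peaks, a mean of 6454 ± 1632 (SD, n = 4). The ratio of means was 3.14, and every KO list was longer than every WT list (exact permutation p = 0.0286, two-sided). With any 1 WT library left out the exact p was 0.0571 or 0.0857. KO peaks covered 12.4 ± 9.47 Mb of the genome and WT peaks 2.29 ± 1.07 Mb (SD, n = 4 each). The median fold over background of the strongest 1000 peaks was 15.02 ± 3.03 in KO and 9.18 ± 0.101 in WT (SD, n = 4; exact permutation p = 0.0286). The fragment density of the ChIP libraries, recovered from the authors' fold and −log10 p values, did not follow list length. It was 2.92, 11.3, 8.11 and 5.87 per kb in KO libraries 1 to 4 and 2.43, 9.94, 13.7 and 14.4 per kb in WT libraries 1 to 4. List length depends on enrichment and calling as well as on the number of acetylated sites. Which sites carried the mark was therefore compared among the 4233 strongest peaks of every library, ranked by −log10 q, with the lists as deposited beside them.

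**Figure D1:**
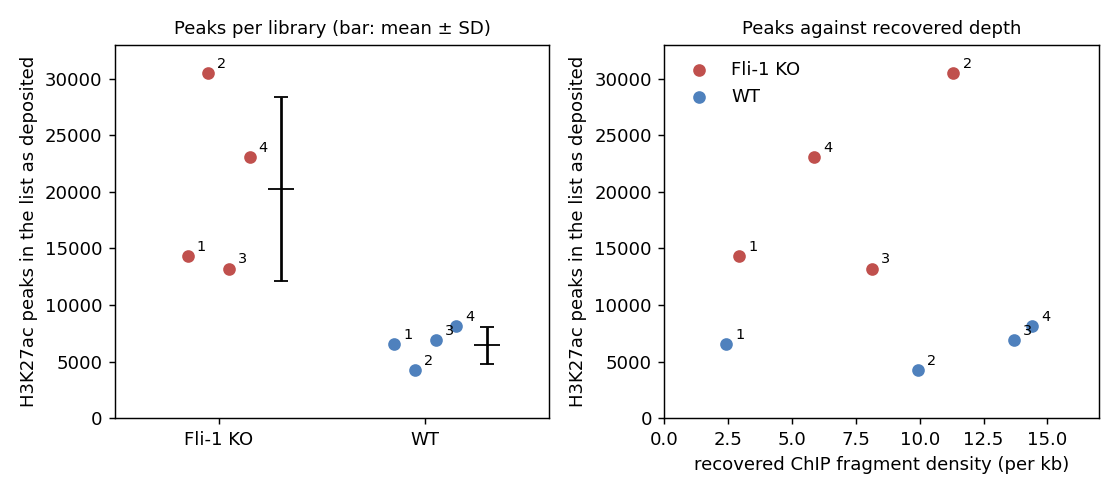
The left panel plots the number of H3K27ac peaks in each library's list as deposited, with the replicate number beside each point and the mean ± SD of the 4 libraries of a genotype. The right panel plots the same counts against the recovered ChIP fragment density per kb: all 4 KO libraries lie above the longest WT list of 8147 peaks, and the WT libraries reach the highest densities.

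Genes with a peak within 1 kb of an annotated gene end differed between the genotypes. Among the 4233 strongest peaks, 1190 genes had such a gene-end peak in all 8 libraries. Another 212 genes had one in all 4 KO libraries and no WT library, and 66 had one in all 4 WT libraries and no KO library. The 175 protein-coding genes of the KO-only set included the DNA replication helicase subunit Mcm7 and the histone deacetylase Hdac2. The 53 of the WT-only set included the stem cell transcription factor Runx1 and the immediate-early factor Egr1. These sets describe rank, not presence. In the lists as deposited all 53 WT-only coding genes had a gene-end peak in at least 1 KO library, 20 of them in all 4. Of the 175 KO-only coding genes, 87 had one in at least 1 WT library. None could have one in all 4, as the list of WT library 2 held only the 4233 peaks already compared. Over all genes the lists as deposited gave 1331 genes in KO only and 0 in WT only, so the WT-only set exists only in lists of equal length. Fisher's exact test per gene, with Benjamini-Hochberg adjustment over 5837 genes, passed 0 genes. Its smallest possible p of 0.0286, reached by 278 genes, gave an adjusted p of 0.5999. With limma on rank scores, a test added after the data were seen, 19 genes ranked higher in KO and 7 in WT at an adjusted p under 0.05, and 1090 passed unadjusted. Without both replicates numbered 1, limma called 0 genes after adjustment and 1170 passed unadjusted.

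Of the 175 KO-only coding genes, 9 were members of a fixed list. They were Mcm7 (chromosome 5, 138164583 to 138172111), the retinoblastoma relative Rbl1 (chromosome 2, 157145893 to 157204534), Hdac2 (chromosome 10, 36974297 to 37001889), the ribosomal protein gene Rpl13 (chromosome 8, 123102350 to 123105244) and Nop16 (chromosome 13, 54584191 to 54590097). They also held the mitochondrial genes Uqcrc2, of respiratory complex III (chromosome 7, 120635189 to 120659523), and Tfam, the mitochondrial transcription factor (chromosome 10, 71225468 to 71238328). The last of the 9 were the stem cell identity list members Hoxa7 (chromosome 6, 52215623 to 52218573) and Sox4 (chromosome 13, 28948919 to 28953699). In the lists as deposited, Rbl1, Rpl13, Nop16, Uqcrc2, Tfam, Hoxa7 and Sox4 had a gene-end peak in 4 KO and 0 WT libraries, and Mcm7 and Hdac2 in 4 KO and 1 WT. The Mcm7 peaks lay at 138170561 to 138172442, which also holds the start of Ap4m1, so they cannot be given to one gene. Higd2a, the neighbour of Nop16 in the KO-only set, was also at 4 KO and 0 WT libraries, so the Nop16 peaks may be shared too. The Sox4 summits lay within the window in only 2 KO libraries. The KO-only genes outside the fixed lists with the best mean rank were the proteasome subunit gene Psmd14 (chromosome 2, 61711694 to 61800376), Ccdc112 (chromosome 18, 46282151 to 46311950) and the caspase gene Casp2 (chromosome 6, 42264902 to 42282508). As deposited, all 3 had a gene-end peak in 4 KO libraries, with Psmd14 in 2 WT libraries and Ccdc112 and Casp2 in 1 WT library each. Their limma adjusted p-values were 0.0355, 0.0355 and 0.0376. The Ccdc112 peak lay outside the gene, at 46280040 to 46281324, with no summit within 1 kb. Tmem139, the neighbour of Casp2 in the KO-only set, was also at 4 KO and 0 WT libraries, so the Casp2 peaks may be shared.

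Of the 53 WT-only coding genes, 10 were members of a fixed list. They included Egr1 (chromosome 18, 34861207 to 34864956), Ier3 (chromosome 17, 35821713 to 35822911) and the antiproliferative gene Btg2 (chromosome 1, 134074865 to 134079155). Cebpd, a myeloid transcription factor (chromosome 16, 15887286 to 15889545), Ncf1, an NADPH oxidase subunit (chromosome 5, 134220053 to 134229628), and Runx1 (chromosome 16, 92601466 to 92826074) were among them. The Ncf1 summits lay within the window in 3 WT libraries. All 6 genes had a gene-end peak in 4 KO and 4 WT libraries in the lists as deposited. Odc1, the first enzyme of polyamine synthesis (chromosome 12, 17544808 to 17551502), had one in 2 KO libraries as deposited. Polr1a, of RNA polymerase I (chromosome 6, 71909053 to 71979435), the splicing gene Snrpd3 (chromosome 10, 75518042 to 75535440) and the sterol receptor gene Nr1h3 (chromosome 2, 91184061 to 91202829) each had one in 3 KO libraries. So did the best-ranked WT-only gene outside the lists, Phrf1 (chromosome 7, 141228477 to 141262751), whose peak is shared with Gm51460 (chromosome 7, 141228206 to 141229616). The Polr1a and Snrpd3 peaks lay outside those genes and inside another annotated gene. The Ier3 peaks also lay within 1 kb of an annotated end of Flot1. These peaks cannot be given to a single gene either.

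**Figure D2:**
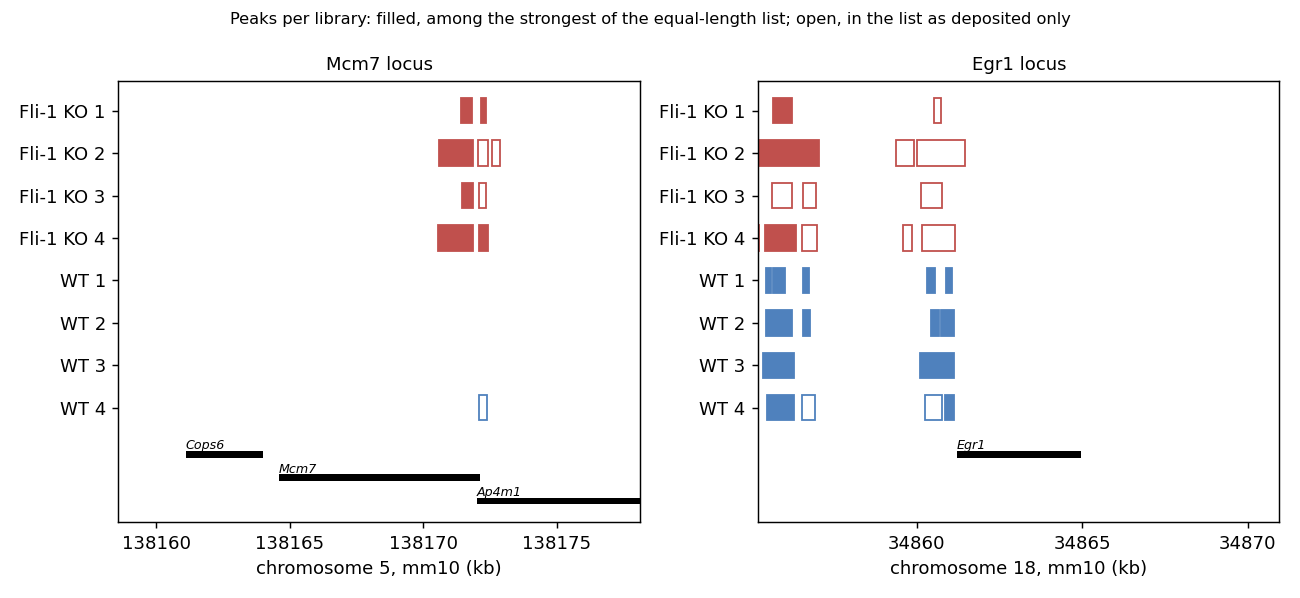
Each row is a library and each box a peak placed by mm10 position in kb, filled if among the 4233 strongest peaks of that library and open if only in the list as deposited. At Mcm7 the filled boxes are in the 4 KO libraries, and at the start of Egr1 they are in the 4 WT libraries while the KO libraries have open ones. Further left in the Egr1 panel, KO libraries 1, 2 and 4 also have filled boxes, at ranks 936, 939 and 2258. KO library 3 has only open ones there.

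Of 28 gene lists fixed before the data were examined, 5 separated the genotypes at the smallest exact p. Cell-cycle genes had gene-end peaks more often in KO, at 12.25 ± 2.99 of 40 genes against 5.25 ± 1.26 in WT (SD, n = 4). The log2 odds ratio against other genes was 1.15 higher in KO (exact permutation p = 0.0286, adjusted p = 0.16). Of the 21 members with any peak, 15 had it in more KO and 3 in more WT libraries. They included the helicase genes Mcm5 (chromosome 8, 75109468 to 75128439; 4 KO and 1 WT library) and Mcm2 (chromosome 6, 88883474 to 88898780; 3 and 0), and the ribonucleotide reductase gene Rrm1 (chromosome 7, 102441695 to 102469771; 3 and 0). Oxidative phosphorylation genes had gene-end peaks at 11.5 ± 0.577 of 27 genes in KO and 5.50 ± 1.73 in WT, a log2 difference of 1.18 (exact permutation p = 0.0286, adjusted p = 0.16). Of 18 members with a peak, 13 had it in more KO and 2 in more WT libraries. Besides Uqcrc2 and Tfam they included the ATP synthase gene Atp5a1 (chromosome 18, 77773768 to 77782869; 3 and 0). With lists of 2116 peaks the difference for oxidative phosphorylation was 0.03 (exact permutation p = 0.971), and with any 1 KO library left out its exact p was 0.0571.

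Lists that ranked higher in WT held few genes. The granulocyte and monocyte list had 5.75 ± 0.5 of 43 genes with a gene-end peak in WT and 3.00 ± 0.816 in KO, a log2 difference of −1.28 (exact permutation p = 0.0286, adjusted p = 0.16; SD, n = 4). The members with the largest differences toward WT were Cebpd, Ncf1 and Cebpb (chromosome 2, 167688915 to 167690432; 2 KO and 4 WT libraries). Of the heptad of stem cell transcription factors, 7 genes that include Fli1, WT libraries had 1.5 ± 0.577 genes and KO libraries 0, a log2 difference of −2.60 (exact permutation p = 0.0286, adjusted p = 0.16). Those genes were Runx1 and Lyl1 (chromosome 8, 84701423 to 84704716; 0 KO and 2 WT libraries). In the lists as deposited the heptad difference was 0.044 (exact permutation p = 0.8286) and that of the granulocyte and monocyte list −0.07 (exact permutation p = 0.629). For Notch pathway genes the counts were 1.5 ± 0.577 and 2.00 ± 0 of 22 genes in KO and WT, a log2 difference of −0.72. The largest difference was at Hhex (chromosome 19, 37434841 to 37440731; 1 KO and 4 WT libraries). KO libraries 2 and 3 had 2 Notch genes, as every WT library did. Only the larger number of other marked genes in KO lists set these 2 libraries apart from WT. The log2 difference for Notch genes was 0.38 in the lists as deposited. With any WT library left out its p was 0.0571 or 0.0857.

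The other 23 lists did not separate the genotypes in this measure. For the ETS family the log2 difference was −0.33 (exact permutation p = 0.143), for stem cell identity genes 0.49 (p = 0.171, but 1.89 as deposited and −1.62 with lists of 2116 peaks, both at p = 0.0286) and for chromatin regulators 0.54 (p = 0.0857, with Hdac2 and Ezh2 among the members). AP-1 and immediate-early genes gave −0.83 (p = 0.114), NF-κB genes −0.60 (p = 0.0571), ribosomal proteins 0.23 (p = 0.686) and housekeeping genes 0.11 (p = 0.771) in the same exact test. The endothelial list, markers of the niche cells, had 1 gene with a gene-end peak in any library and a difference of −0.32 (exact p = 0.486). The mesenchymal and the silent-tissue lists had 0 genes. With 0 genes in every library these lists still gave −0.32 (exact p = 0.0571), which is the offset that the larger number of marked genes in KO lists puts on every list. That number was 4142 ± 386 in KO and 3375 ± 245 in WT (SD, n = 4; exact permutation p = 0.0571). The remaining lists gave 0.09 for mast cells and basophils (exact p = 0.971), −0.55 for erythroid (p = 0.257), −0.22 for megakaryocyte (p = 0.571), −0.72 for lymphoid (p = 0.286) and −0.14 for dendritic genes (p = 0.543). They gave −0.17 for niche receptors (exact p = 0.286), −0.45 for p53 targets (p = 0.171), −0.58 for apoptosis (p = 0.0857), −0.45 for cell-cycle inhibitors (p = 0.314) and −0.01 for MYC targets (p = 0.971). Interferon genes gave 0.30 (exact p = 0.457), glycolysis −0.38 (p = 0.114) and lipid genes −0.69 (p = 0.0571). No list passed adjustment over the 28 lists. As deposited, 15 of the 28 differences had the opposite sign, that of AP-1 and immediate-early genes among them. In the lists as deposited 8 lists reached p = 0.0286, all higher in KO, with a smallest adjusted p of 0.1 by the same exact permutation test. They were the cell cycle, oxidative phosphorylation, stem cell identity, lymphoid, ribosomal protein, interferon, chromatin regulator and housekeeping lists.

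**Figure D3:**
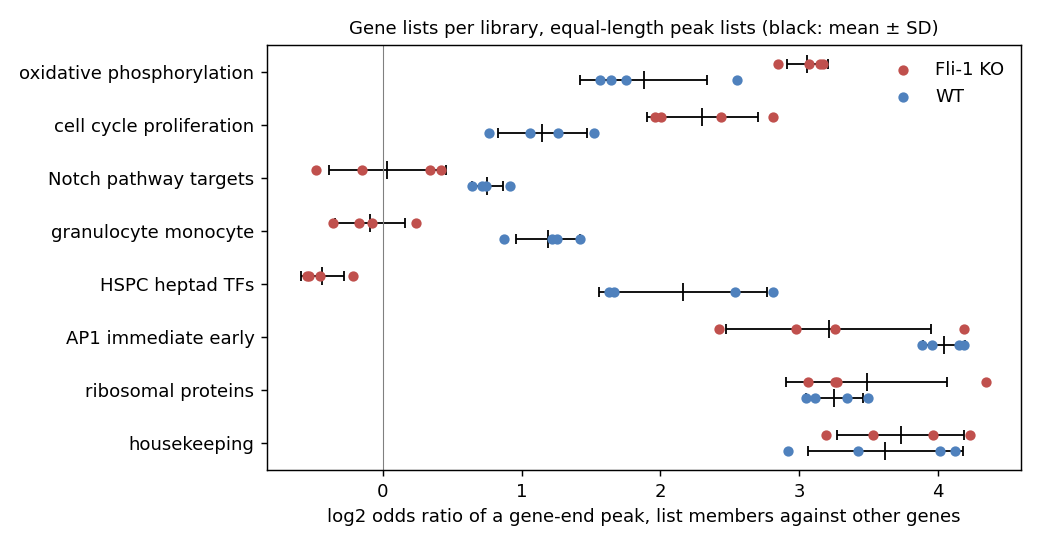
Points are the 8 libraries, black bars the mean ± SD of 4, and the horizontal axis the log2 odds ratio of a gene-end peak in list members against all other genes, among the 4233 strongest peaks. The 5 upper lists separate the genotypes without overlap, and the 3 lower ones (AP-1, ribosomal, housekeeping) do not.

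The share of a library's peaks lying within 50 kb of listed genes adds distal peaks. AP-1 and immediate-early loci held 0.927% ± 0.140 of KO peaks and 1.59% ± 0.162 of WT peaks (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0889). The difference in the lists as deposited was −0.61 percentage points, also at p = 0.0286 by exact permutation. NF-κB loci held 0.750% ± 0.0952 of KO and 1.01% ± 0.116 of WT peaks, and granulocyte and monocyte loci 0.602% ± 0.0734 and 0.833% ± 0.0933. Oxidative phosphorylation loci held 0.567% ± 0.0193 and 0.431% ± 0.0297. In total 9 lists reached an exact permutation p of 0.0286, 8 of them higher in WT, and none passed adjustment. The others were heptad, dendritic, endothelial, glycolysis and housekeeping loci. As deposited, 3 of the 9 (AP-1, NF-κB, and granulocyte and monocyte loci) still had that p. Oxidative phosphorylation loci then differed by 0.0451 percentage points (exact permutation p = 0.286), and the exact p of the 5 other lists was 0.171 to 0.8. A region called as several peaks counts more than once in this measure, and peak widths differed. The median width of the 4233 strongest peaks was 832 ± 483 bp in KO and 322 ± 108 bp in WT (SD, n = 4; exact permutation p = 0.0857).

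Regions were compared without gene annotation. Peaks merged over the 8 equal-length lists formed 8771 regions, of which 1010 had a peak in every library, 192 in KO only and 76 in WT only. As deposited, 1883 regions were KO-only and 1 was WT-only, so the WT-only set of regions also depends on lists of equal length. Of the KO-only regions 89.1% lay within 1 kb of a gene end, and of the WT-only regions 59.2%, with 24 of the WT-only regions inside gene bodies and 7 between genes. The KO-only regions were wider, with a median of 1316 bp against 548 bp, and a wider region reaches a gene end more easily. Fisher's exact test passed 0 of 7761 regions after adjustment, and 268 had its smallest p. The share of all peaks at gene ends was 77.8% ± 3.57 in KO and 68.6% ± 4.30 in WT in the equal-length lists (SD, n = 4; exact permutation p = 0.0286). In the lists as deposited it was 51.8% ± 8.68 and 61.7% ± 7.52 (exact permutation p = 0.143), so the direction turned with list length. Peaks of the equal-length lists were wider in KO (mean of the median widths 832 bp against 322 bp), which may contribute to the equal-length difference. On average, the Jaccard index (shared over combined covered bases) was higher within a genotype than across genotypes, with overlapping ranges. The index is capped where covered lengths differ. The equal-length lists covered 1.73 to 6.94 Mb in KO and 0.966 to 2.10 Mb in WT, so peak width may contribute to the difference. The mean Jaccard index was 0.346 within KO (0.189 to 0.494 over 6 pairs), 0.341 within WT (0.216 to 0.507 over 6 pairs) and 0.229 between (0.0831 to 0.343 over 16 pairs), a difference of 0.114 that 1 of the 35 splits of the libraries reached (exact permutation p = 0.0286).

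**Figure D4:**
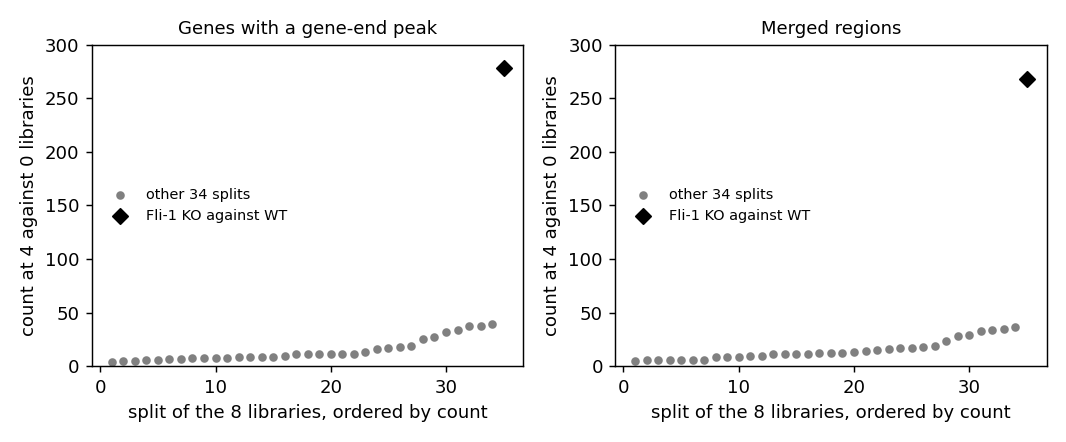
Each point is 1 of the 35 ways to split the 8 libraries into 4 and 4, with the count of genes (left) or regions (right) that have a peak in all libraries of one side and none of the other. The genotype split gives 278 genes and 268 regions, and the highest other split 39 and 37.

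Clusters of peaks were compared next. Peaks within 12 kb of each other were joined and the 100 domains with most covered bases taken per library. Those sets differed in width, since WT-only domains covered as little as 786 bp in WT library 1 (at Lrrc25) and KO-only domains 1322 bp or more in KO library 1 (at Zc3h4). They overlapped 557 genes, 6 of them in all 8 libraries, among them Kmt2e, Mnt, Vmp1 and Neat1. A KO-only domain in 4 of 4 libraries lay over the histone genes H1f2 (chromosome 13, 23738807 to 23739531) and H3c3 (chromosome 13, 23745042 to 23745521). Others lay over the chromatin remodelling genes Chd2 (chromosome 7, 73426652 to 73541746) and Arid2 (chromosome 15, 96287522 to 96405463), over Zc3h4 (chromosome 7, 16399583 to 16437696) and over Tgif1 (chromosome 17, 70844205 to 70853532). WT-only domains lay over Ncf1, Pnrc2 (chromosome 4, 135870917 to 135873846) and Lrrc25 (chromosome 8, 70616844 to 70620850). Another lay over the histone methyltransferase gene Nsd3 (chromosome 8, 25601601 to 25719667) and also over Letm2, so it cannot be given to one gene. In all, 11 genes were KO-only and 8 WT-only, of which Fisher's exact test passed 0 after adjustment and 19 at an unadjusted p of 0.0286. Neighbouring genes under the same domain, such as Chd2 and Chaserr or Tgif1 and Gm36856, were each counted, so there were fewer domains than genes. Without WT library 1, 12 genes were KO-only and 20 WT-only.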

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

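The tests of ChIP depth and of other splits of the libraries for genes were chosen after the results they measure were seen, as was the limma test of rank scores.

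In 5 of 76 groups of 4 libraries, 1 library stood apart from the other 3 by its log2 odds ratio for a gene list. KO library 1 had −2.04 for mast cell, basophil and eosinophil genes, where the other KO libraries had −0.72 to −0.63. WT library 1 had 0.12 for lymphoid genes, where the other WT libraries had −0.93 to −0.82, and 0.00325 for interferon genes, where the others had −1.04 to −0.94. WT library 2 had −0.52 for endothelial genes, where the others had −2.25 to −1.98. KO library 4 had 4.35 for ribosomal protein genes, where the others had 3.07 to 3.28. Chance sets apart about 1 in 20 groups, and the first 4 of these values rest on lists with at most 9 genes with any peak. No biological explanation was tested for these single libraries.

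The KO lists were longer than the WT lists. Higher ChIP depth in KO is argued against, since the mean recovered density was 7.06 per kb in KO and 10.1 per kb in WT. With KO −log10 p values scaled to the WT calling depth, the shortest KO list still held 12799 peaks and the longest WT list 8037. Immunoprecipitation efficiency and a gain of acetylation cannot be told apart, because both would raise the fold of the strongest peaks, 15.02 in KO against 9.18 in WT. The genotype therefore stays open as an explanation, beside handling of the libraries that followed genotype and a control input that may have been shared within a genotype.

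In lists of equal length, 1 of the 35 splits of the libraries (the genotype split) gave as many genes, 278 against 39 for the highest other, as many regions, 268 against 37, as many domain genes, 19 against 3, and as many genes called by limma, 26 against 0. A chance assignment of these 8 libraries would put the genotype split first in 1 of 35 cases, the smallest share this design can give. That argues against such an assignment but does not exclude it, and the counts are not independent, as they come from the same peak lists. Variation between animals or cultures stays open, and enrichment quality that followed genotype may contribute. So may the control, as each genotype had a single input library. Calling density was the same, 5.25 per kb, in KO libraries 2 to 4, and 4.62 per kb in WT libraries 2 to 4. If the lists of a genotype shared that input, its noise would enter all of them and cannot be told apart from genotype. Among replicates 3 and 4, 972 genes were at 2 against 0 by genotype and at most 207 in the other splits, but calling density (5.25 in KO and 4.62 per kb in WT) and fragment length (256 and 242 bp, 233 and 234 bp) still followed genotype there and cannot be told apart from it. Of the 278 genes 276 lay on autosomes, so genes of the sex chromosomes made up little of the count. Chromosome X held only 1.01% of KO and 0.856% of WT peaks in these lists, so the test could hardly have come out otherwise. A sex difference between animals acting on autosomal genes was not tested and stays open, as peaks on chromosome Y numbered 6 in KO library 3, 5 in KO library 4 and 0 in the other 6 libraries.

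The WT-only genes included myeloid genes such as Cebpd and Ncf1. Mature myeloid cells in the WT libraries are a possible explanation, although the sort for lineage-negative cells would remove them before culture. Of 10 abundant granulocyte and monocyte genes (Mpo, Elane, Prtn3, Ctsg, S100a8, S100a9, Lyz2, Ltf, Ngp and Camp), 0 had a gene-end peak in more WT than KO libraries. Only Mpo had one at all, in 1 KO list as deposited, so this argues only against a share of such cells large enough to give peaks. A loss of rank in KO because many other peaks gained signal stays open.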

How the results depend on the processing

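Whole gene bodies, summits, limma, regions covered to at least 50% and omission of both replicates numbered 1 were chosen after seeing the data. The cause of the changes below was not tested unless stated. The motif comparison and its alternatives were not run, for want of a genome sequence. An overlap of 50% of a peak could not be applied to merged regions as worded, and regions covered to at least 50% replaced it.

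The difference in peaks per library was 13809, and 10404 to 16155 with each library left out, where the exact p rose to 0.0857 at most and missed the threshold without any 1 of the 4 WT libraries. The gene-end share difference of 9.26 percentage points ranged from 7.26 to 10.8 with each library left out (exact p = 0.0571 without KO library 4 or WT library 1, 2 or 4), but was −9.87 in the lists as deposited and −12.8 at a −log10 q of at least 5. The similarity difference of 0.114 ranged from 0.0962 to 0.148 (exact p = 0.0571 without WT library 1).

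In the lists as deposited there were 1884 regions, 1331 genes and 31 domain genes at 4 against 0, and 8 gene lists at the smallest p. Lists of 2116 peaks gave 136 regions, 140 genes and 10 domain genes, as shorter lists hold fewer, and 4 gene lists, with oxidative phosphorylation, heptad and Notch genes lost. A −log10 q of at least 5 gave 1779 regions, 1422 genes and 9 gene lists. Ranking by fold gave 3 gene lists, with granulocyte and monocyte and Notch genes lost. Notch genes also lost the call with 2.5 kb windows and with summits. Whole gene bodies gave 10 gene lists. With each library left out the ranges were 320 to 408 regions, 316 to 437 genes, 20 to 32 domain genes, 4 to 6 gene lists and 4 to 9 lists by locus share. The counts of regions and genes that moved by over 1.5 times were 408 regions and 437 genes without KO library 1, and 407 regions and 32 domain genes without WT library 1. The lists by locus share also moved that far, from 9 to as few as 4. Of those 9 lists, 4 or 5 kept the smallest p without any 1 KO library, and 7 to 9 without any 1 WT library. Limma called 26 genes.

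Without both replicates numbered 1, the differences were 15831 peaks and 0.182 in similarity, with 580 regions and 555 genes at 3 against 0. The smallest exact p is then 0.1, so 0 gene lists could reach the threshold, and limma called 0 genes after adjustment, with 1170 at an unadjusted p under 0.05.

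With the replicate number as a block, peaks per library still differed by 13809 and gene-end share by 9.26 points, both at p = 0.125, the smallest an exact sign-flip test of 4 pairs gives, so 0 gene lists and 0 lists by locus share could pass. Limma with the block called 54 genes. Correlations of KO and WT libraries of the same number were 0.208, −0.00855, 0.0844 and 0.0188. For KO libraries 1 and 3 the same number gave the highest correlation. The deviations of KO libraries 2 and 4 correlated best with those of WT libraries 4 and 3. The numbers therefore did not pair all libraries, and whether the replicates numbered 1 shared a batch was not tested.

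As deposited, 15 of 28 lists turned direction by gene-end peaks and 10 of 28 by locus share. Those that had the smallest p before or after were heptad (0.044), Notch (0.38) and lymphoid (0.65) genes, and by locus share dendritic (0.0131), ETS (0.0987) and megakaryocyte (0.0779 percentage points) genes. By locus share 3 of 9 lists kept the smallest p. At a −log10 q of at least 5, 13 lists turned, of which ETS (0.41), niche receptor (0.61) and Notch (0.30) genes had the smallest p before or after. With lists of 2116 peaks 10 turned, of which stem cell identity genes (−1.62) did. Cell-cycle genes kept their direction and the smallest p in every alternative chosen before the data were seen except the block, where the smallest possible p was 0.125.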

Other observations

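The gene families were chosen after the data were seen.

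Chromosome X held 1.48% of KO peaks and 0.805% of WT peaks in the lists as deposited (exact permutation p = 0.0286). In lists of equal length the shares were 1.01% and 0.856% (exact permutation p = 0.257), so the length of the lists may account for the difference.

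Of 11 gene families taken by symbol, 5 reached an exact permutation p of 0.0286 with an adjusted p of 0.0629. Minichromosome maintenance, condensin and cohesin genes had gene-end peaks at 18 of 28 genes in KO and 8.75 in WT, tRNA genes at 25.25 and 11.25 of 402, proteasome genes at 19.75 and 12.25 of 57, splicing factors at 28 and 21.75 of 49, and Klf genes at 5 and 6.5 of 17. A hypothesis was that families of ubiquitously expressed genes carry more peaks in KO lists. Of the 5 families tested for it, 3 (proteasome, tRNA and splicing) were higher in KO at the smallest exact p, which leaves it open. CCT chaperonin and mitochondrial ribosomal protein genes were also higher in KO, by log2 differences of 0.78 and 0.32 (exact permutation p = 0.0571 and 0.114).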
